A study of Arabidopsis thaliana with 305 samples.

How the data were processed

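RNA-seq libraries were made from leaf discs of 6-week-old Arabidopsis thaliana plants grown under short days and infiltrated by hand, per the labels' protocols. The infiltrated strain is Pseudomonas fluorescens Pf0-1 by the series description, while the protocol in the labels names only strains of Pseudomonas syringae, for growth curves, so the strain could not be checked there. The bacteria carried an empty vector (EV) or delivered the effector AvrRps4, AvrRpt2 or AvrRpm1. Leaves were collected without infiltration (T0) and at 0.5, 4 and 8 h after it. Messenger RNA was captured on oligo(dT), copied with random hexamers and sequenced as 50-base single-end reads on an Illumina HiSeq4000, per the labels' protocols.

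Gene counts were deposited by the authors, who, per the submitters' processing notes, checked reads with FastQC 0.11.7, trimmed them with Trimmomatic 0.36, aligned them to TAIR10 with HISAT2 2.1.0 and counted reads per gene with featureCounts from Subread, whose version is not given. The notes state no normalisation of the counts, no statistical test and no strand setting, so reads of overlapping or antisense genes cannot be told apart. The deposited table holds 25320 genes. A TAIR10.1 annotation table was used for gene names alone, and 24966 of the gene identifiers matched it, while 354 did not. No coordinates were used.

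Groups, replicates and libraries were taken from the labels. The 305 libraries fall into 52 groups of genotype, bacterium and time. In 149 replicates, 2 libraries carry the same group and replicate number, and their counts were summed, while 7 replicates have 1 library. The labels do not say whether such pairs are repeats of sequencing, of library preparation or of sampling, so n rests on this reading, and AvrRps4 in Col-0 at 4 h gave 131 genes summed and 633 unsummed. This gave 156 replicates, with n = 3 in every group. The 2 libraries of a replicate differed by more than counting error in all 149 pairs, with a chi-square per degree of freedom of 1.7 to 31.71 and a median of 4.54 over genes with a mean count of at least 50. In 597 pairs of libraries from different replicates of the same group the median was 9.15.

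Library totals ran from 3128554 to 23257821 counts with a median of 5477113, and replicate totals from 4276389 to 28926563 with a median of 11021790. Where a group had 0 counts of a gene, a fold change was given as a lower bound against 3 counts over the group. Where it had 1 to 3 counts, the counts were given in place of a fold change. Such floors cover counting error alone, since PCR copies are not independent molecules, whereas the p-values measure the spread between samples.

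Counts were normalised by the trimmed mean of M values (TMM) and tested with edgeR 4.0.16 in R 4.3.3, using a robust quasi-likelihood F test after filtering by expression within groups. The normalisation factors lay between 0.6549 and 1.497. A single model held the means of all 52 groups, with no covariate, and 19687 genes were tested in each of 57 contrasts. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. With no change at all, exact p-values would put a share of about 0.05 of the genes under an unadjusted 0.05. Each effector was compared with EV at the same time within a genotype, EV with T0 within Col-0, and each mutant with Col-0 at T0 and under EV at 4 h. Differences between genotypes in the response to an effector were tested as interactions, at 4 and 8 h against Col-0 and at 4 h between both incomplete mutants. Values quoted as CPM, counts scaled to equal library size, are TMM-normalised and given as mean ± SD over n = 3, log2 fold changes are given ± SE, and CPM of single libraries are not TMM-normalised.

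The comparisons, thresholds, model, gene lists, naming rule and alternatives were chosen before the data were examined. The 15 lists were written from general knowledge of Arabidopsis: salicylic acid pathway, N-hydroxypipecolic acid pathway, pattern-triggered immunity, camalexin and indole defence, sensor NLR and EDS1-node genes, helper NLR genes, jasmonate pathway, ethylene pathway, abscisic acid response, touch response, photosynthesis, circadian clock, and markers of guard cells, of epidermis and trichomes, and of vascular tissue. They hold 228 genes, of which 227 were measured. Each list was tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. The p-values were adjusted over all 855 pairs of list and contrast, of which 245 passed. With the correlation estimated from the data, 14 pairs passed.

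Genes were named by a fixed rule. It took the 5 helper NLR genes, the reference genes ICS1, PR1, PAD4, FMO1 and FRK1, and in each described list the 2 to 4 passing members with the largest changes, or the 1 or 2 largest where none passed. For effectors against EV in Col-0 at 4 h, EV against T0 at 4 h and the helperless interaction at 4 h, it also took the 5 largest rises and 5 largest falls among passing genes with a mean log2 CPM of at least 3 and no overlap between replicates. For the interaction between both incomplete mutants and for mutants against Col-0 it took the 3 largest of each.

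A retained response was computed without a test, as the mean over the genes that rose in Col-0 at 4 h of each replicate's log2 CPM minus the mean of its genotype's EV replicates. Its SD leaves out the spread of the EV replicates. A second version scored each replicate on genes chosen without it. Genes chosen by their rise in Col-0 may inflate its value, so in both versions shares of Col-0 may be too low.

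The model was tested on simulated counts with 200 of 19587 genes changed in Col-0 with AvrRps4 at 4 h. It called 93 of 100 genes changed 8-fold, 73 of 100 changed 4-fold and 14 of 19387 unchanged genes. For the interaction of helperless with Col-0, 79 of 100 and 50 of 100 were called, with 4 unchanged genes. No gene was called in the wrong direction, and camera gave an unadjusted p under 0.05 for 0 of 200 unchanged lists. The simulated genes varied independently, so this cannot show how often camera calls unchanged lists of correlated genes. The edgeR rates hold for the simulated spread, which AvrRps4 replicates may exceed.

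Alternatives planned in advance were relative log expression (RLE) factors, no filter on low counts, DESeq2 1.42.0 with a Wald test, libraries left unsummed, fits on the groups of 1 comparison alone, the replicate number as a block, each replicate left out in turn, and, for retained responses, a prior count of 0.5. A fit without 10 libraries whose helper gene counts go against their label was added after the data were seen.

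Replicate numbers were judged to pair samples where every pair of same-numbered samples had a correlation over 0.1 between deviations from the group means, which was decided before fits were compared. This held in 17 of the 57 contrasts: the 3 effectors in Col-0 at 0.5 h, AvrRpt2 in Col-0 at 4 and 8 h, EV at 4 h against T0, AvrRpt2 at 4 h in nrg1 and helperless, AvrRps4 at 4 h in helperless, AvrRpm1 at 8 h in nrg1, the helperless interaction for AvrRpt2 at 4 h, and the 6 contrasts of a mutant with Col-0. The pairing comes from the data alone, since the labels name no shared day or batch.

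The simulations, splits and alternatives used fixed seeds. Tables were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The comparisons of effectors with EV in the mutants at 0.5 h were left out of the planned comparisons.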

Results

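Transcript counts were measured in leaves of 4 Arabidopsis genotypes to ask how far the responses to 3 bacterial effectors need the helper NLRs, immune proteins that act downstream of the NLR receptors that detect effectors. The genotypes were the accession Col-0, an nrg1.1 nrg1.2 mutant (nrg1), an adr1 adr1-L1 adr1-L2 mutant (adr1) and a mutant lacking both helper families (helperless). The bacterium, by the series description, was Pf0-1, a non-pathogenic strain equipped to inject proteins into plant cells, and it carried either an empty vector (EV) or a single effector. AvrRps4 is detected by the receptor pair RRS1 and RPS4, AvrRpt2 by RPS2 and AvrRpm1 by RPM1. Each genotype was sampled before infiltration (T0) and with each of the 4 strains at 0.5, 4 and 8 h, with n = 3 in each of 52 groups. The 305 libraries held a median of 5477113 counts.

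ADR1 and ADR1-L1, helper genes disrupted in adr1 and helperless, had higher counts in those mutants than in Col-0. Under EV at 4 h, ADR1 had 845 ± 126 CPM in adr1 and 803 ± 111 in helperless (SD, n = 3), against 8.36 ± 2.06 in Col-0. ADR1-L1 had 2920 ± 218 and 2790 ± 77.1 against 200 ± 40.4 CPM. ADR1-L2 had 29.4 ± 1.29 and 28.0 ± 3.43 against 67.4 ± 13.8 CPM. NRG1.1 had 22.4 ± 2.19 CPM in nrg1 and 28.5 ± 3.6 in Col-0, and NRG1.2 had 13.9 ± 8.48 and 13.9 ± 5.29, so neither transcript checks the nrg1 labels. In infiltrated leaves the ratio of ADR1-L1 to ADR1-L2 counts was 1.15 to 5.56 in 137 libraries labelled Col-0 or nrg1 and 32.64 to 658.97 in 135 labelled adr1 or helperless. In 10 further libraries it went against the label. These were both libraries of replicate 3 labelled Col-0 under EV at 8 h (97.96 and 57.01), both of replicate 2 labelled adr1 with AvrRpm1 at 8 h (1.82 and 2.35), and both of replicate 3 labelled adr1 under EV at 8 h (3.07 and 2.89). The rest were both of replicate 3 labelled helperless under EV at 8 h (2.47 and 2.06), 1 of replicate 3 labelled nrg1 under EV at 8 h (44.18) and 1 of replicate 3 labelled nrg1 with AvrRpm1 at 4 h (24.03). At T0 the ranges met, at 1.51 to 3.67 in 12 libraries and 2.39 to 42.16 in 11, so the ratio does not check those labels. All 305 libraries were kept under their labels, and values without the 10 are given wherever they change a call. Without the 10, n = 2 is left under EV at 8 h in Col-0, adr1 and helperless and with AvrRpm1 at 8 h in adr1.

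**Figure D1:**
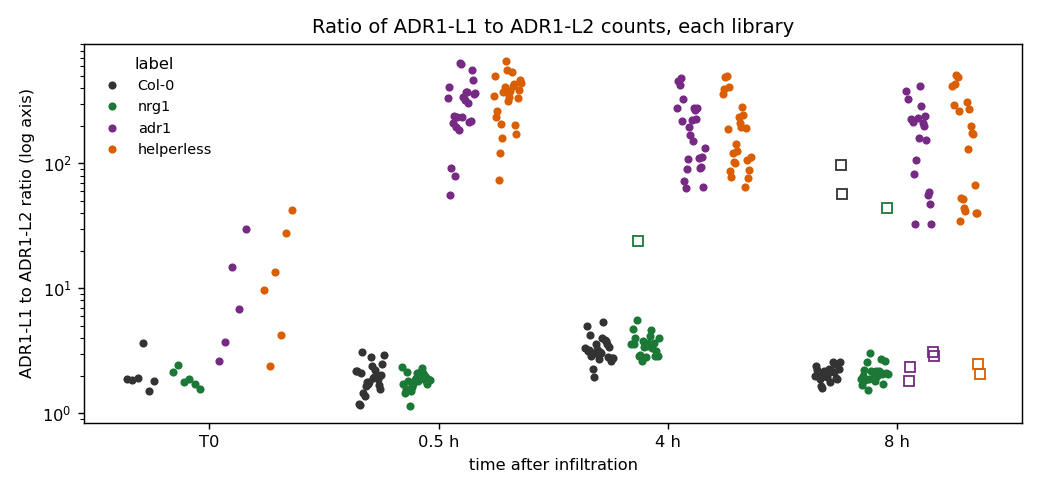
Ratio of ADR1-L1 to ADR1-L2 counts on a log axis against time after infiltration, with 1 point per library coloured by its labelled genotype. Open squares mark the 10 libraries on the other side of a ratio of 10 from their label, 9 of them at 8 h, and the T0 libraries run from 1.51 to 42.16.

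The comparison of EV with T0 in Col-0 describes what infiltration, the bacterium and the time of day did together. At 0.5 h, genes of pattern-triggered immunity, the response to conserved bacterial molecules, were already high. The ubiquitin ligase gene PUB23 rose by 7.41 ± 0.57 on the log2 scale (SE, n = 3, edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.5e-20), and the transcription factor genes WRKY40 and WRKY22 rose by 6.69 ± 0.57 and 6.67 ± 0.57. Of 30 genes on this list, 28 rose and 1, the receptor kinase gene FRK1, fell, in the same numbers when adjusted over the list alone. Their median was 4.41 (camera adjusted p = 1.4e-29, and adjusted p = 0.0486 with an estimated correlation). FRK1 changed by -1.78 ± 0.69 (edgeR adjusted p = 0.0362), which did not pass without replicate 2 (-0.97, adjusted p = 0.441) or replicate 3 (-2.37, adjusted p = 0.0727). All 3 touch genes rose, TCH4 by 6.53 ± 0.72, TCH3 by 3.86 ± 0.41 and TCH2 by 3.63 ± 0.41 (camera adjusted p = 1.3e-05, and adjusted p = 0.0354 with an estimated correlation). Jasmonate genes followed, with 20 of 26 up (20 up and 1 down adjusted over the list alone), led by the repressor gene JAZ8 at 7.94 ± 0.72 and the lipoxygenase gene LOX4 at 7.74 ± 0.67.

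Receptor and helper genes also rose within 0.5 h. NDR1, a membrane protein gene needed by several receptors, rose by 4.67 ± 0.36 and the receptor gene ZAR1 by 3.81 ± 0.27, with 11 of 14 sensor NLR and EDS1-node genes up. Of the 5 helper genes 4 rose, NRG1.1 by 3.00 ± 0.27, ADR1-L2 by 2.16 ± 0.40, ADR1-L1 by 2.13 ± 0.53 and NRG1.2 by 2.11 ± 0.54. Both counts were the same adjusted over the list alone. In other lists GRX480 rose by 7.14 ± 0.79 and NIMIN2 by 5.20 ± 0.73 (salicylic acid, 10 of 21 up and 1 down, 11 and 1 adjusted over the list alone). FOX1 rose by 6.93 ± 1.03 and WRKY33 by 5.13 ± 0.49 (camalexin, 8 of 12 up and 1 down), while ERF6 rose by 6.32 ± 0.74 and ACS7 by 6.22 ± 1.22 (ethylene, 9 of 16 up and 1 down). The camera adjusted p for the jasmonate, sensor, helper, salicylic acid, camalexin and ethylene lists were 1.9e-15, 5.4e-09, 0.00913, 3.0e-04, 2.8e-05 and 1.8e-04. In the same order these lost their calls, at adjusted p = 0.185, 0.182, 0.185, 0.559, 0.422 and 0.278 with an estimated correlation. PAD4, whose product works with EDS1, rose by 1.94 ± 0.51 (edgeR adjusted p = 0.00145, and 1.52 with adjusted p = 0.0991 without replicate 2). ICS1, which makes the salicylic acid precursor, stood at 1.00 ± 0.55 (adjusted p = 0.168), and FMO1 and PR1 had 4 and 1 counts over the group against 1 and 1 at T0. None of 39 photosynthesis genes passed by edgeR (median -0.05, camera adjusted p = 0.708). In all, 2780 genes rose and 1815 fell.

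By 4 h under EV, photosynthesis transcripts had fallen. The Rubisco small subunit genes RBCS1B and RBCS2B fell by 5.76 ± 1.16 and 4.05 ± 0.93 on the log2 scale and the antenna gene LHCB2.2 by 3.97 ± 1.01 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.2e-05, 1.0e-04 and 4.1e-04, n = 3). All 39 listed genes fell, adjusted over the list alone too, with a median of -2.73 (camera adjusted p = 9.2e-08, and adjusted p = 0.81 with an estimated correlation). FRK1 went from 6.4 ± 3.81 CPM at T0 to 1730 ± 758 (8.07 ± 0.82), PROPEP2, an immune peptide precursor, rose by 7.65 ± 0.90 and NHL10 by 7.36 ± 0.88. Among 30 genes of pattern-triggered immunity 29 rose (camera adjusted p = 6.6e-14, and adjusted p = 0.34 with an estimated correlation). The camalexin genes CYP71A12 and PAD3 rose by 7.47 ± 0.83 and 6.90 ± 0.89 (10 of 12 up), and the jasmonate-responsive genes ANAC019 and ANAC055 by 7.33 ± 0.86 and 5.82 ± 0.73 (18 of 26 up and 1 down, 19 and 2 adjusted over the list alone). In the salicylic acid list 12 of 21 rose and 2 fell, with WRKY62 at 5.92 ± 0.96, NIMIN1 at 5.73 ± 0.95, PBS3 at 5.23 ± 0.73 and ICS1 at 2.15 ± 0.57, while WRKY38 went from 0 to 84 counts, 77 of them in replicate 1, at least 32.1-fold over the group but only 2.76-fold without that replicate. PR1 had 1 count at T0 and 0 at 4 h, and FMO1 had 1 and 71. The ethylene synthesis gene ACS2 rose by 6.86 ± 0.66 (10 of 16 up and 1 down), PAD4 by 2.40 ± 0.52 and SAG101 by 2.07 ± 0.36 (7 of 14 up). The camera adjusted p of these 5 lists were 1.3e-05, 1.5e-05, 0.00315, 0.00465 and 0.0185, which became adjusted p = 0.382, 0.655, 0.669, 0.473 and 0.807 with an estimated correlation.

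The remaining lists did not pass camera at 4 h under EV, though single members moved. All 4 N-hydroxypipecolic acid genes rose, UGT76B1 by 5.44 ± 0.94 (median 5.34, or 4.47 with 2 genes set to the floor, adjusted p = 0.131, and 0.0346 without replicate 3). The clock gene LHY fell by 4.49 ± 0.83 and CCA1 by 3.32 ± 0.78 while PRR5 rose by 5.46 ± 0.75 and FKF1 went from 1 to 649 counts (7 of 13 up and 4 down, camera adjusted p = 0.271). HAI1 and HAI2 of the abscisic acid response rose by 5.07 ± 0.82 and 4.50 ± 0.87 (5 of 16 up, 0.208), TCH3 and TCH4 by 1.86 ± 0.38 and 1.75 ± 0.58 (3 of 3 up, 0.253). NRG1.2 and ADR1-L1 rose by 1.55 ± 0.54 and 1.43 ± 0.52 (2 of 5 up, 0.65). The guard cell genes MYB60 and GORK fell by 1.97 ± 0.34 and 1.23 ± 0.47 (2 of 8 down, 0.404). The vascular gene SULTR2;1 fell by 1.86 ± 0.47 (1 of 11 up and 3 down, 0.307) and the epidermal gene PDF1 by 4.2 ± 0.93 (3 of 9 up and 4 down, 0.731). The 5 largest rises were AT4G12500 (8.92 ± 0.93), NRT2.6 (8.57 ± 1.42), AT4G12490 (8.53 ± 0.99), ELI3-2 (8.45 ± 1.02) and EARLI1 (8.35 ± 0.89), where AT4G12490, AT4G12500 and EARLI1 are close copies, so their counts are uncertain. The 5 largest falls were AT2G10940 (-7.29 ± 1.47), AT5G02760 (-6.33 ± 1.17), NdhM (-6.26 ± 1.31), AT2G15020 (-6.22 ± 0.92) and ESM1 (-5.95 ± 1.52). In all, 4597 genes rose and 5145 fell. Of 46 named genes that passed, 5 were lost without replicate 1 (FMO1, WRKY38, GORK, NRG1.2 and ADR1-L1, edgeR adjusted p of 0.0592 to 0.122), 2 without replicate 2 (GORK and ADR1-L1, 0.0503 and 0.175) and 2 without replicate 3 (ADR1-L1 and TCH4, 0.0541 and 0.0984).

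At 8 h under EV these changes went on. RCA, which activates Rubisco, fell by 5.43 ± 0.87 and LHCB1.2 by 5.58 ± 1.21, within 39 of 39 photosynthesis genes down (edgeR adjusted p = 1.1e-07 and 4.8e-05, n = 3). NHL10 rose by 7.69 ± 0.89 and FRK1 by 7.39 ± 0.79, within 27 of 30 genes of pattern-triggered immunity up, both counts being the same adjusted over the list alone. LHY and CCA1 fell by 7.95 ± 1.00 and 6.95 ± 0.94. ICS1 rose by 1.95 ± 0.56 (1.40 with adjusted p = 0.0503 without replicate 3) and PAD4 by 1.73 ± 0.51, while PR1 and FMO1 had 165 and 190 counts against 1 and 1 at T0. ADR1-L1 rose by 3.66 ± 0.57, NRG1.2 by 2.63 ± 0.55 and ADR1 by 4.88 ± 0.92, but without the 10 libraries ADR1-L1 stood at 1.79 (adjusted p = 8.8e-05) and ADR1 at 1.28 (0.0561). In total 3798 genes rose and 4518 fell, and 3818 and 4118 without the 10 libraries.

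AvrRps4 at 4 h raised salicylic acid genes in Col-0. ICS1 went from 68.9 ± 40.9 CPM under EV to 633 ± 460 (log2 change 3.20 ± 0.59, edgeR adjusted p = 3.7e-04, n = 3). It was higher in 3 of 3 replicates than in any EV replicate. PAD4 rose by 2.32 ± 0.51 (adjusted p = 0.0056). The salicylic acid target genes PR5, PR2 and DLO1 rose by 6.03 ± 1.27, 5.72 ± 1.04 and 5.38 ± 0.87, and PR1 had 3569, 1 and 1 counts in the 3 replicates against 0 in every EV replicate, at least 1000-fold over the group. These 4 genes rested on replicate 1, and without it PR2 stood at 2.05 (adjusted p = 0.539). In the salicylic acid list 8 of 21 rose, or 12 adjusted over the list alone (median 1.60, camera adjusted p = 1.2e-15, and adjusted p = 0.0354 with an estimated correlation). ALD1 and FMO1, which make N-hydroxypipecolic acid, a signal of systemic resistance, rose by 4.66 ± 0.89 and 4.54 ± 0.92 (2 of 4 up, median 2.74, camera adjusted p = 8.1e-05, and adjusted p = 0.163 with an estimated correlation). EDS1 rose by 1.79 ± 0.48 (adjusted p = 0.0481) but did not pass with RLE factors, without the filter, in DESeq2, without the 10 libraries or with the replicate block (adjusted p of 0.0536 to 0.0943). VSP2, a jasmonate-responsive gene, rose by 4.93 ± 1.22 (adjusted p = 0.0226) but did not pass with any replicate left out (adjusted p of 0.112 to 0.383).

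The 5 largest rises with AvrRps4 at 4 h that met the naming rule were PUB54 (4.02 ± 0.76), AT1G26390 (4.00 ± 0.77), WAK3 (3.58 ± 0.93), CYP76C6 (3.25 ± 0.65) and NUDT6 (3.22 ± 0.86). WAK3 had an edgeR adjusted p of 0.0349 and 0.0575 in DESeq2, and NUDT6 0.0452 and 0.0696 with RLE factors. In all, 131 genes rose and 0 fell by edgeR, where 2119 genes had an unadjusted p under 0.05 and DESeq2 called 100 genes. With only the comparison's groups in the fit 0 genes passed, and all 13 named genes it tested were lost, ICS1 and PAD4 included (adjusted p of 0.235 to 0.557). Leaving out replicate 1, 2 or 3 gave 116, 9 and 188 genes. Of 15 named genes that passed, 11 were lost without replicate 2, ICS1, PAD4, ALD1 and FMO1 among them (log2 changes of 1.04 to 5.42, adjusted p of 0.383 to 1), 6 without replicate 1 (0.0906 to 0.933) and 4 without replicate 3 (0.062 to 0.112). FRK1 stood at -0.18 ± 0.60 (adjusted p = 0.951), and the pattern-triggered immunity list had 0 of 30 genes passing. Photosynthesis genes leaned up with no member passing (median 0.86, LHCB2.2 at 1.66 ± 0.92, camera adjusted p = 4.0e-04), but not without replicate 2 (0.329) and at adjusted p = 0.939 with an estimated correlation. The other lists did not pass camera. Those with a passing member were the sensor NLR and EDS1-node genes (2 of 14 up, PAD4 and EDS1, adjusted p = 0.179) and jasmonate (1 of 26 up, 2 adjusted over the list alone, 0.209, where the median was -0.06, the mean 0.27 and the test downward). Lists with none were camalexin (CYP71A13 2.06 ± 0.85, adjusted p = 0.0965), helper genes (NRG1.2 1.32 ± 0.52, 0.06), abscisic acid (COR15A 1.88 ± 0.99, 0.269), clock (RVE1 -0.81 ± 0.53, 0.431), epidermis (PDF1 2.12 ± 1.00, 0.557) and ethylene (PDF1.2 1.1 ± 1.07, 0.724). The same held for guard cells (GORK 0.94 ± 0.47, 0.849), touch (TCH3 1.21 ± 0.37, 0.4, 1 up adjusted over the list alone), vascular (SWEET12 0.72 ± 0.44, 0.345) and pattern-triggered immunity (PROPEP2 1.05 ± 0.59, 0.725). In the clock, epidermis, guard cell and pattern-triggered immunity lists the test pointed down while the median was 0.02, 0.06, 0.04 and 0.09. Calls appeared without replicate 1 for the sensor, camalexin, helper and ethylene lists (1.4e-05, 1.4e-04, 0.00826 and 0.0169), without replicate 2 for abscisic acid (9.1e-04), without replicate 3 for jasmonate and pattern-triggered immunity (0.00997 and 0.0442) and without the 10 libraries for helper genes (0.014).

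AvrRpt2 at 4 h raised salicylic acid genes in Col-0. ICS1 reached 1030 ± 116 CPM (log2 change 3.90 ± 0.61, edgeR adjusted p = 3.8e-06, n = 3) and PAD4 1020 ± 182 CPM (3.31 ± 0.53). Both were higher in 3 of 3 replicates than any EV replicate. The transporter gene EDS5 rose by 3.26 ± 0.56, the regulator gene SARD1 by 3.20 ± 0.62 and PBS3 by 4.17 ± 0.68. In the salicylic acid list 7 of 21 rose (10 up and 1 down adjusted over the list alone, median 1.45, or 1.31 with PR1 at the floor, camera adjusted p = 6.6e-14, and adjusted p = 0.0458 with an estimated correlation). FMO1 rose by 4.37 ± 0.91 and ALD1 by 3.29 ± 0.85 (2 of 4 up). The camalexin list had 5 of 12 up, or 9 adjusted over the list alone, among them CYP79B2 (2.72 ± 0.72), CYP71A12 (2.15 ± 0.63) and MYB51 (2.07 ± 0.50). The kinase genes MKK4 and MPK3 rose by 1.93 ± 0.44 and 1.79 ± 0.39 and the oxidase gene RBOHD by 1.46 ± 0.37 (4 of 30 pattern-triggered immunity genes up, 7 adjusted over the list alone), while FRK1 stood at 0.35 ± 0.60 (adjusted p = 0.906). The helper gene NRG1.2 rose by 1.96 ± 0.53 (1 of 5, camera adjusted p = 4.1e-04, and adjusted p = 0.0458 with an estimated correlation). EDS1 and SNC1 rose by 2.51 ± 0.49 and 1.03 ± 0.26 (3 of 14 up with PAD4), TCH3 by 1.86 ± 0.38 (1 of 3) and ERF6 by 1.98 ± 0.60 (1 of 16). SNC1 did not pass with RLE factors, in DESeq2, with libraries unsummed or with only the comparison's groups in the fit (changes of 0.98 to 1.0), nor ERF6 with RLE factors (adjusted p = 0.0575). PR1 had 4 counts over the group against 0.

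The camera adjusted p for AvrRpt2 were 1.5e-07 for camalexin, 2.1e-06 for sensor genes, 2.9e-06 for pattern-triggered immunity, 0.00237 for N-hydroxypipecolic acid and 0.00986 for touch. They became adjusted p = 0.235, 0.34, 0.669, 0.34 and 0.278 with an estimated correlation. The ethylene list (0.0355) did not pass without replicate 2 or 3 (0.246 and 0.0604), and the photosynthesis list (median -0.37, 0.0177) did not pass without replicate 1 or 2 (0.293 and 0.0515), with adjusted p = 0.671 and 0.974 with an estimated correlation. The largest rises by that rule were BON3 (4.75 ± 0.77), PUB54 (4.64 ± 0.78), BAP2 (4.47 ± 0.71), AT1G26390 (4.37 ± 0.78) and PBS3. The falls were LBD39 (-1.5 ± 0.45) and AT2G39870 (-1.48 ± 0.45), at edgeR adjusted p of 0.0454 and 0.0448. In all, 479 genes rose and 10 fell. The total was 356, 5 and 349 without replicate 1, 2 or 3, for reasons not tested. Without replicate 2 all 24 named genes were lost (log2 changes of -1.43 to 4.67, edgeR adjusted p of 0.0629 to 0.96), against 4 without replicate 1 (LBD39, AT2G39870, CYP71A12 and SNC1, adjusted p up to 0.171) and 7 without replicate 3 (LBD39, AT2G39870, CYP79B2, CYP71A12, MYB51, NRG1.2 and ERF6, up to 0.294). Without the 10 libraries CYP71A12 and ERF6 did not pass (0.0536 and 0.0615). With no filter LBD39, AT2G39870 and ERF6 were lost (0.0553 to 0.0588), and with only the comparison's groups in the fit LBD39 (0.0708).

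AvrRpm1 at 4 h changed more genes than the other effectors, 1754 up and 371 down. FMO1 rose by 5.80 ± 0.96 (edgeR adjusted p = 5.1e-06, n = 3). ICS1 reached 885 ± 428 CPM (3.68 ± 0.60) and PAD4 691 ± 378 CPM (2.74 ± 0.52). PBS3, EDS5 and SARD1 rose by 3.76 ± 0.67, 3.34 ± 0.56 and 2.92 ± 0.61 (9 of 21 salicylic acid genes up, 11 up and 1 down adjusted over the list alone, median 1.42). Camalexin genes rose, CYP71A13 by 2.92 ± 0.87, CYP71A12 by 2.66 ± 0.65 and CYP79B2 by 2.50 ± 0.71 (7 of 12, 9 adjusted over the list alone). The peptide receptor gene PEPR2 rose by 2.47 ± 0.50 and the peptide precursor gene PROPEP1 by 1.88 ± 0.52 (9 of 30, 10 adjusted over the list alone), and FRK1 stood at -0.12 ± 0.60 (adjusted p = 0.926). In the jasmonate list 5 of 26 rose, LOX4 by 2.15 ± 0.52 and JAZ8 by 1.79 ± 0.53. ALD1 rose by 4.30 ± 0.88 (2 of 4 with FMO1), ERF6 by 2.86 ± 0.62 and ACS6 by 1.82 ± 0.44 (3 of 16) and TCH4 by 1.94 ± 0.58 and TCH3 by 1.91 ± 0.38 (2 of 3). EDS1 rose by 1.73 ± 0.48 (2 of 14 with PAD4) and the helper gene NRG1.1 by 1.34 ± 0.26 (1 of 5). SWEET11, a vascular sugar transporter gene, fell by 1.35 ± 0.37 (1 of 11), and PR1 had 5 counts over the group against 0.

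The camera adjusted p for AvrRpm1 were 9.2e-06 for salicylic acid, 1.4e-04 for pattern-triggered immunity, 1.5e-04 for camalexin, 0.00986 for sensor genes, 0.0122 for jasmonate, 0.0127 for N-hydroxypipecolic acid and 0.0383 for touch. In that order they became adjusted p = 0.376, 0.801, 0.507, 0.771, 0.9, 0.479 and 0.424 with an estimated correlation. The jasmonate call was lost without replicate 3 (0.0605), the sensor call without replicate 2 (0.0592) and the touch call without replicate 1 or 2 (0.125 and 0.0775). Ethylene (0.167), helper genes (0.146), abscisic acid (0.278, and 0.0331 without replicate 1) and vascular markers (0.891) did not pass. The largest rises after FMO1 were BON3 (5.73 ± 0.81), AT1G26390 (5.13 ± 0.80), AT1G14550 (5.10 ± 0.74) and BAP2 (5.06 ± 0.73). The largest falls were AT5G44575 (-2.24 ± 0.63), OPT6 (-2.06 ± 0.52), CYP71B2 (-2.05 ± 0.43), AT2G39870 (-1.96 ± 0.46) and AT1G65500 (-1.94 ± 0.48). Leaving out replicate 1, 2 or 3 gave 2008, 495 and 1172 genes. Of 31 named genes that passed, 5 were lost without replicate 1, 12 without replicate 2 and 8 without replicate 3 (edgeR adjusted p of 0.0502 to 0.834), and ICS1, PAD4 and FMO1 were kept in each.

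**Figure D2:**
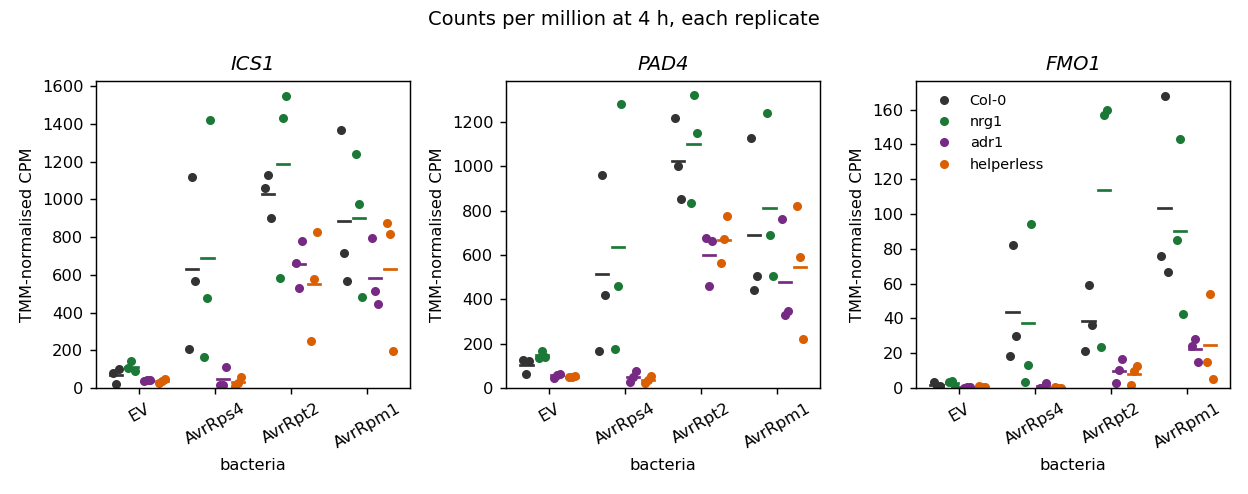
TMM-normalised CPM of ICS1, PAD4 and FMO1 at 4 h for each bacterium, with 1 point per replicate coloured by genotype and a bar at the mean of n = 3. ICS1 averaged 633 CPM with AvrRps4 in Col-0 and 30.3 in helperless, against 1030 and 552 with AvrRpt2.

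At 0.5 h the effectors were hardly apart from EV in Col-0. AvrRps4 raised AT3G45210 by 2.1, the auxin-responsive gene SAUR15 by 3.98 and OFP13 by 3.39, all named after their values were seen, and no other gene passed in edgeR. Without replicate 1, 2 or 3 the count was 2, 0 and 6, and it was 6 with replicate numbers as a block, which paired the samples here. AvrRpt2 and AvrRpm1 gave 0 genes in edgeR, where 248 and 884 genes had an unadjusted p under 0.05 and DESeq2 called 1 and 2.

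By 8 h the salicylic acid response to AvrRps4 in Col-0 had reached PR1, a marker of that hormone. PR1 had 312 ± 27.7 CPM against 3.62 ± 3.05 under EV (6.42 ± 1.14, n = 3), PBS3 rose by 3.71 ± 0.67, EDS5 by 3.52 ± 0.57 and ICS1 by 3.12 ± 0.58. In the salicylic acid list 10 of 21 rose (15 adjusted over the list alone, median 1.78, camera adjusted p = 4.0e-12, and adjusted p = 0.0629 with an estimated correlation). ALD1 and FMO1 rose by 5.60 ± 0.90 and 5.29 ± 0.92 (3 of 4 up, 4 adjusted over the list alone, camera adjusted p = 4.4e-06, and adjusted p = 0.0629 with an estimated correlation). PAD4 rose by 3.53 ± 0.54 (4 of 14 sensor genes up, 5 adjusted over the list alone, camera adjusted p = 9.6e-05, and adjusted p = 0.506 with an estimated correlation), and FRK1 stood at 0.09 ± 0.60. With AvrRpt2, PR1 rose by 5.78 ± 1.11, FMO1 by 5.74 ± 0.94, ICS1 by 3.44 ± 0.59, PAD4 by 3.45 ± 0.54 and the camalexin gene CYP71A13 by 5.65 ± 0.99. AvrRpm1 raised CYP71A13 by 5.57 ± 0.99, FMO1 by 4.27 ± 0.88, JAZ8 by 3.52 ± 0.57 and ICS1 by 2.01 ± 0.56 (1.77 without replicate 2, not passing). It raised PAD4 by 1.37 ± 0.50 (1.14 and 1.15 without replicate 1 or 2, not passing) and PR1 by 3.05 ± 0.99, which did not pass in DESeq2 (edgeR adjusted p = 0.00847, DESeq2 0.102) or without the 10 libraries (2.47, 0.0506). AvrRps4 changed 755 genes up and 241 down, AvrRpt2 2000 and 901, and AvrRpm1 3374 and 2324. The library pair labelled Col-0 under EV enters all 3 contrasts, and without the 10 libraries the totals were 565, 2429 and 5474 against 996, 2901 and 5698. Leaving out a replicate gave 324 to 1282, 1369 to 2422 and 4046 to 5899, lowest without replicate 2 in each. ADR1 under AvrRps4 stood at -3.43 ± 0.85 but at 0.18 without the 10 libraries and 0.05 without replicate 3.

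**Figure D3:**
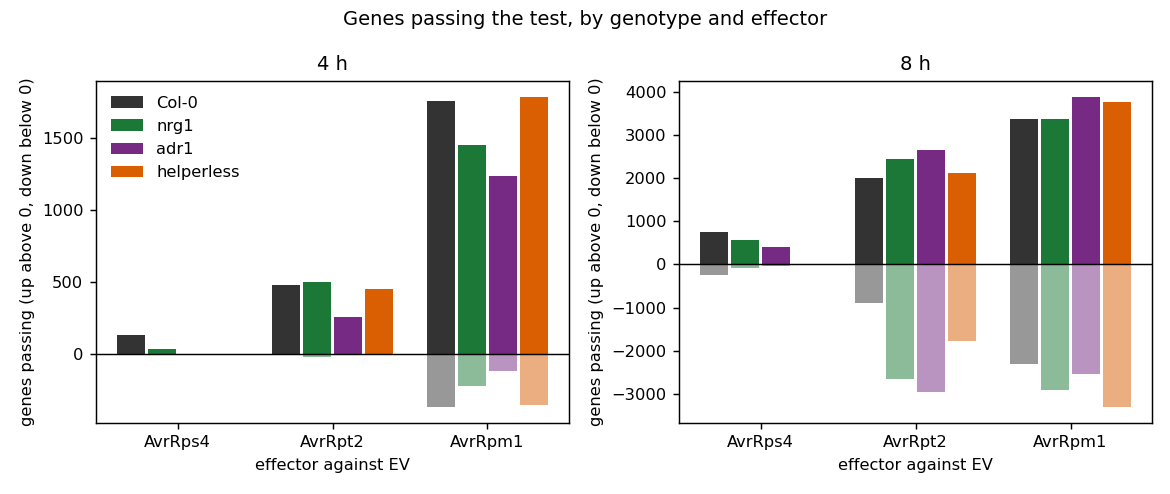
Number of genes passing the edgeR test for each effector against EV, as bars above 0 for rises and below 0 for falls, coloured by genotype, in panels by time. With AvrRps4 at 4 h the bars are 131 genes in Col-0, 32 in nrg1 and 0 in adr1 and helperless.

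In the mutants the comparison asks how much of each effector's response remains without a helper family. With AvrRps4 at 4 h, ICS1 in nrg1 went from 111 ± 27.6 to 686 ± 651 CPM (2.62 ± 0.57, edgeR adjusted p = 0.0141, n = 3). PAD4 rose there by 2.12 ± 0.51 (0.042), PBS3 by 2.73 ± 0.64 and FMO1 by 3.73 ± 0.88 (0.0328, and 0.111 in DESeq2). In adr1, ICS1 had 39.7 ± 4.11 and 49.1 ± 54.8 CPM (0.31 ± 0.54, adjusted p = 0.899), and PAD4 and FMO1 stood at -0.14 ± 0.49 and 1.31 ± 1.14. In helperless, ICS1 had 37.0 ± 12.2 and 30.3 ± 23.9 CPM (-0.29 ± 0.54), PAD4 50.6 ± 2.88 and 37.5 ± 17.6 CPM (-0.43 ± 0.49) and FMO1 -1.26 ± 1.23, each at adjusted p = 1. In nrg1, 32 genes rose, against 0 in adr1 and 0 in helperless by edgeR, where 1298 and 237 genes had an unadjusted p under 0.05 and DESeq2 also called 0 and 0. The nrg1 count was 71, 2 and 0 without replicate 1, 2 or 3 and 0 with only the comparison's groups in the fit, and ICS1, PAD4, PBS3 and FMO1 did not pass without replicate 2 or 3 (adjusted p of 0.238 to 0.581), nor FMO1 without replicate 1 (up to 0.0698) or PAD4 without the filter (0.0548). The salicylic acid list passed upward in nrg1 (2 of 21 up, median 0.73, or 0.87 with 2 genes at the floor, camera adjusted p = 4.6e-04, and adjusted p = 0.579 with an estimated correlation) but not without replicate 3 (0.755, downward). It passed downward in adr1 (median -0.16, 0.02, and adjusted p = 0.801 with an estimated correlation), though not without replicate 1 or 2 (0.574 and 0.122), and did not pass in helperless (0.0985, and 0.00222 without replicate 3).

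Whether these responses differ between genotypes was tested as an interaction. For AvrRps4 at 4 h, the log2 response of helperless minus that of Col-0 was -3.49 ± 0.79 for ICS1, -5.95 ± 1.36 for ALD1, -6.22 ± 1.40 for PR2, -5.80 ± 1.5 for FMO1 and -2.75 ± 0.71 for PAD4. None passed (edgeR adjusted p = 0.0814, 0.0814, 0.0814, 0.187 and 0.187, n = 3 in each of 4 groups). PR2 had 0.0454 in DESeq2. In adr1 the differences were -2.90 ± 0.78 for ICS1, -2.45 ± 0.70 for PAD4 and -7.08 ± 1.44 for PR2 (adjusted p = 0.698, 0.698 and 0.0586), where PR2 had 0.00229 in DESeq2 and ICS1 stood at -4.84 (0.0208) without replicate 3. In nrg1 they were -0.58 ± 0.76 for ICS1, -0.20 ± 0.69 for PAD4 and -0.82 ± 1.16 for FMO1. PR2 passed in nrg1 (-7.00 ± 1.39, adjusted p = 0.0394) on replicate 1 of Col-0, and stood at -3.65 without replicate 1, -6.73 without replicate 2 and -7.48 without replicate 3, passing in none. As a list, the salicylic acid genes responded less than in Col-0 in helperless (median -1.71, camera adjusted p = 4.3e-16, and adjusted p = 0.0354 with an estimated correlation) and in adr1 (-1.87, or -1.77 with 3 genes at the floor, 1.3e-28, and adjusted p = 0.00132 with an estimated correlation). In nrg1 the median was -0.44 (2.2e-06, adjusted p = 0.34 with an estimated correlation, and 0.426 without replicate 2). The N-hydroxypipecolic acid list passed downward in helperless (-3.39, 1.2e-05, and adjusted p = 0.0809 with an estimated correlation) and adr1 (8.0e-07, and adjusted p = 0.0458 with an estimated correlation) but not in nrg1 (0.289, and 8.4e-04 without replicate 3). Between adr1 and nrg1, ICS1, NIMIN1 and PAD4 differed by -2.32 ± 0.78, -2.73 ± 1.04 and -2.25 ± 0.70 (adjusted p = 1 for each). The salicylic acid list passed downward (median -1.05, or -1.19 with 3 genes at the floor, camera adjusted p = 3.4e-09), as did the N-hydroxypipecolic acid list (-1.73, 3.1e-04). Both calls were lost, at adjusted p = 0.163 and 0.21 with an estimated correlation. By gene, edgeR called 1, 0 and 0 for nrg1, adr1 and helperless against Col-0 and 0 for adr1 against nrg1, where 231, 419, 849 and 332 genes had an unadjusted p under 0.05 and DESeq2 called 3, 2, 3 and 1. Each of these numbers at an unadjusted p lies under a share of 0.05 of the 19687 genes tested. They are thus no sign of weaker differences, and 0 calls do not show that there are none. Leaving out a replicate gave at most 1 gene in any of the 4 contrasts, and leaving out the 10 libraries 2 in helperless. With the replicate block the counts were 1, 1, 4 and 0, although these contrasts did not meet the pairing rule.

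AvrRpt2 and AvrRpm1 raised salicylic acid genes at 4 h in all 3 mutants. In helperless, ICS1 reached 552 ± 291 CPM with AvrRpt2 (3.90 ± 0.61, n = 3) and 628 ± 377 with AvrRpm1 (4.08 ± 0.61), PAD4 rose by 3.73 ± 0.55 and 3.43 ± 0.54, and FMO1 by 3.69 ± 0.97 and 5.28 ± 1.00. In adr1, ICS1 rose by 4.05 ± 0.61 and 3.88 ± 0.61, PAD4 by 3.41 ± 0.54 and 3.08 ± 0.53 and FMO1 by 4.58 ± 1.04 and 5.75 ± 1.06. In nrg1 the rises were 3.42 ± 0.59 and 3.01 ± 0.58 for ICS1, 2.91 ± 0.53 and 2.47 ± 0.52 for PAD4 and 5.35 ± 0.94 and 5.02 ± 0.93 for FMO1. With AvrRpt2, 10, 8 and 10 of the 21 salicylic acid genes rose in nrg1, adr1 and helperless (camera adjusted p = 1.5e-11, 3.1e-16 and 6.6e-15, and adjusted p = 0.0706, 0.0354 and 0.0389 with an estimated correlation). With AvrRpm1, 12, 8 and 11 rose (4.6e-06, 6.3e-07 and 2.8e-06, and adjusted p = 0.348, 0.284 and 0.34 with an estimated correlation). The helperless interaction was 0.00 ± 0.84 for ICS1 and 0.42 ± 0.69 for PAD4 with AvrRpt2 and 0.40 ± 0.76 and 0.69 ± 0.69 with AvrRpm1 (edgeR adjusted p = 1 for each). The salicylic acid list did not pass for either (camera adjusted p = 0.585 and 0.391, the former 0.0275 without replicate 2).

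Over all genes, AvrRpt2 at 4 h changed 520 genes in nrg1, 256 in adr1 and 456 in helperless, and AvrRpm1 1672, 1355 and 2140. Without replicate 2 these were 21, 45 and 92 and then 146, 272 and 432, and without replicate 3 the AvrRpt2 counts were 146, 119 and 210. Without replicate 2, ICS1 and PAD4 in nrg1 did not pass (edgeR adjusted p of 0.0528 to 0.0895). FMO1 with AvrRpt2 did not pass in adr1 or helperless without any 1 replicate (adjusted p of 0.0513 to 0.48), nor with AvrRpm1 in helperless without replicate 2 (0.0987). As interactions with Col-0, edgeR called 0 genes for AvrRpt2 in nrg1, adr1 and helperless, with 173, 167 and 147 at an unadjusted p under 0.05 and 1, 0 and 1 in DESeq2. It called 0 for AvrRpm1, with 200, 276 and 323 and 1, 0 and 1 in DESeq2. Between adr1 and nrg1 it called 0 and 0, with 183 and 180 at an unadjusted p under 0.05 and 1 and 1 in DESeq2. For these interactions every number at an unadjusted p lies under a share of 0.05 of the 19687 genes tested, and 0 calls do not show equal responses.

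The genes that rose in Col-0 at 4 h give a retained response. The 131 AvrRps4 genes averaged 2.34 ± 0.53 on the log2 scale in Col-0 (SD without the spread of EV, n = 3), 1.42 ± 0.67 in nrg1, 0.31 ± 0.32 in adr1 and -0.07 ± 0.01 in helperless, that is 60.7%, 13.1% and -2.92% of Col-0. Choosing genes without the replicate scored lowered these to 1.03 ± 0.17, 0.55 ± 0.60, -0.17 ± 0.46 and -0.40 ± 0.06. In nrg1 the value was -0.03 without replicate 2, when 9 genes were left, and in helperless it was 0.07, 0.13 and 0.11 without replicate 1, 2 or 3. The 479 AvrRpt2 genes kept 93.8% in nrg1, 85.4% in adr1 and 94.6% in helperless, and the 1754 AvrRpm1 genes 86.9%, 85.5% and 93.8%. With AvrRpt2, choosing genes without the replicate scored gave 2.69 ± 0.94, 2.55 ± 1.06, 2.49 ± 0.85 and 2.68 ± 0.94 in Col-0, nrg1, adr1 and helperless, and leaving out replicate 2, when 5 genes were left, 3.32, 3.24, 3.67 and 3.38.

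**Figure D4:**
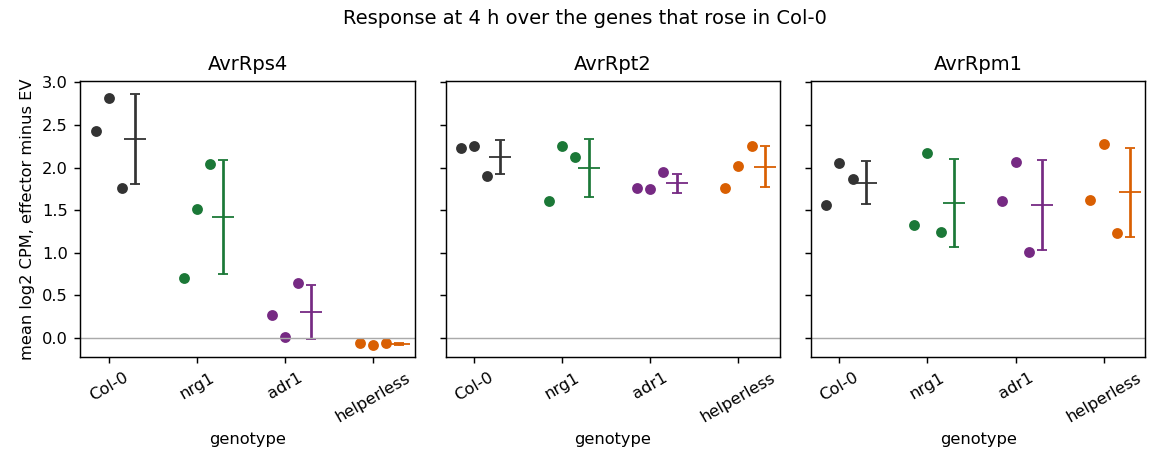
Mean log2 change against EV at 4 h over the genes that rose in Col-0, by effector and genotype, with 1 point per replicate and the mean ± SD of n = 3, without the spread of EV. AvrRps4 genes averaged 2.34 in Col-0 and -0.07 in helperless, while AvrRpt2 genes averaged 2.13 and 2.01.

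At 8 h the AvrRps4 response of helperless fell short of Col-0 by gene as well. Its response minus that of Col-0 was -7.12 ± 1.43 for PR1, -6.45 ± 1.19 for ALD1, -6.22 ± 1.24 for FMO1, -3.93 ± 0.72 for PAD4, -3.76 ± 0.88 for PBS3 and -2.81 ± 0.78 for ICS1 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 6.9e-04, 2.4e-04, 6.2e-04, 2.1e-04, 0.00634 and 0.03, n = 3 in each of 4 groups). NIMIN1, EDS5, SARD4, CYP71A13, WRKY18 and TCH3 also passed, and FRK1 stood at -0.23 ± 0.84. ALD1, FMO1 and PAD4 still passed without the 10 libraries, and the other 9 did not (adjusted p of 0.0537 to 0.506, PR1 among them). Without replicate 1, 2 or 3, 3, 8 and 10 of the 12 named genes were lost, and PR1 was kept in each but had an adjusted p of 0.0523 in DESeq2. With only the comparison's groups in the fit PR1, PBS3, SARD4 and TCH3 did not pass (adjusted p of 0.0538 to 0.12), nor did SARD4 with no filter (0.0577). In all, 48 genes were higher and 346 lower, against 2 and 71 without the 10 libraries and totals of 265, 81 and 31 without replicate 1, 2 or 3. Leaving out the 10 libraries leaves n = 2 under EV in Col-0 and helperless, so calls lost there need not come from wrong labels. The salicylic acid list passed downward (9 of 21 down, median -2.49, camera adjusted p = 1.1e-12, and adjusted p = 0.055 with an estimated correlation), as did the N-hydroxypipecolic acid list (3 of 4 down, -4.43, 6.3e-06, and adjusted p = 0.066 with an estimated correlation). In adr1 these lists had medians of -0.97 and -1.75 (4.8e-07 and 4.7e-05, and adjusted p = 0.278 and 0.138 with an estimated correlation). In nrg1 the salicylic acid list had -0.44 (3.6e-04, adjusted p = 0.571 with an estimated correlation, and 0.055 without replicate 1).

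Against their own EV at 8 h, AvrRps4 changed 578 genes up and 78 down in nrg1, 401 and 38 in adr1 and 0 in helperless by edgeR, where 910 genes had an unadjusted p under 0.05 and DESeq2 called 0. Without the 10 libraries the totals were 561 in nrg1, 172 in adr1 and 0 in helperless, and with only the comparison's groups in the fit they were 0, 0 and 0. Leaving out replicate 1, 2 or 3 gave 2074, 301 and 87 genes in nrg1 and 1227, 46 and 60 in adr1. The retained response at 8 h was 2.75 ± 0.03 in Col-0, 2.32 ± 0.63 in nrg1, 1.3 ± 0.92 in adr1 and 0.01 ± 0.14 in helperless (SD without the spread of EV, n = 3). Leaving out a replicate gave 1.8 to 3.41 in Col-0, 1.4 to 3 in nrg1 and -0.23 to 0.34 in helperless, which stood at 0.27 without the 10 libraries. Choosing genes without the replicate scored gave 2.42 ± 0.72, 1.53 ± 0.43, 0.43 ± 1.71 and -0.48 ± 0.56. AvrRpt2 changed 5126, 5626 and 3899 genes in nrg1, adr1 and helperless and AvrRpm1 6301, 6453 and 7100, against 4837, 5343 and 3263 and 6182, 4887 and 6353 without the 10 libraries. Of these, the AvrRpt2 counts were 2873 in nrg1 without replicate 3 and 3415 and 975 in adr1 and helperless without replicate 2, and the AvrRpm1 count in adr1 was 4152 without replicate 2. For AvrRpm1 at 8 h, RLE in place of TMM moved the median gene by 0.123 in nrg1 and 0.108 in helperless. Without the 10 libraries edgeR called 0 genes in the interactions of nrg1 and adr1 with Col-0 for any effector and of helperless for AvrRpt2 and AvrRpm1.

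Without an effector few genes passed between mutants and Col-0, which does not show small differences at n = 3. AT1G07920 is an elongation factor gene of a family with near-identical copies. At T0 it was higher by 2.65 ± 0.30 in nrg1, 2.75 ± 0.30 in adr1 and 2.72 ± 0.30 in helperless (edgeR adjusted p = 6.0e-10, 1.4e-10 and 2.2e-10, n = 3). Under EV at 4 h it was higher by 2.24 ± 0.30, 2.2 ± 0.30 and 2.12 ± 0.30. MRD1, named after its values were seen, had 62, 41 and 68 counts in the mutants at T0 against 0 in Col-0, at least 22.8-fold, 18.6-fold and 22.6-fold higher over the group (14.1, 11.8 and 14.2 at the lowest with a replicate left out), and 74, 59 and 59 against 1 under EV at 4 h. Leaving out a replicate ended the MRD1 call in nrg1, adr1 or helperless at T0 or under EV in at least 1 case each (adjusted p up to 1). AT4G38550 was higher in nrg1 at both (2.15 ± 0.39 and 1.89 ± 0.39), and DIC2 and CAF1a in adr1 at T0 (2.56 ± 0.54 and 2.54 ± 0.52), but each lost its call when some replicate was left out (adjusted p up to 1). ADR1 was higher under EV at 4 h by 6.66 ± 1.00 in adr1 and 6.59 ± 0.99 in helperless, and ADR1-L1 by 3.87 ± 0.57 and 3.8 ± 0.57. Without replicate 2 ADR1, ADR1-L1 and MRD1 did not pass, at adjusted p of 0.058 to 0.212 in adr1 and 0.0571 to 1 in helperless. ADR1-L2 stood at -1.20 ± 0.39 and -1.27 ± 0.39 (adjusted p = 1 for both), and without the 10 libraries it passed in helperless (-1.29, 0.0193). Without them ADR1 and ADR1-L1 also passed at T0, at 2.78 and 2.2 in adr1 and 2.85 and 2.26 in helperless (adjusted p up to 0.00881). In all, 3, 15 and 2 genes were higher at T0 in nrg1, adr1 and helperless and 3, 4 and 4 under EV at 4 h, 0 were lower by edgeR, and DESeq2 called 3, 36 and 6 and 4, 5 and 7. Without replicate 2 each of these 6 counts was 1, without replicate 3 the adr1 count at T0 was 3, and without the 10 libraries helperless had 6 and 8.

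Salicylic acid genes were lower as a list under EV at 4 h in adr1 (median -0.68, or -0.74 with 2 genes at the floor, camera adjusted p = 7.6e-08, and adjusted p = 0.211 with an estimated correlation) and helperless (-0.93, or -0.98, 5.3e-12, and adjusted p = 0.0636 with an estimated correlation). The adr1 call was lost without replicate 1 (0.0675). No member passed by edgeR in either, NIMIN1 standing at -2.46 ± 0.73 in adr1 (adjusted p = 1) and WRKY70 at -2.43 ± 0.67 in helperless (0.717). WRKY38 had 8 and 5 counts over the group against 84 in Col-0, of which 77 were in replicate 1 (adjusted p = 1 and 0.515). The N-hydroxypipecolic acid list was lower too (median -1.40 and -1.05, 2.0e-04 and 0.00325, FMO1 at -2.17 ± 1.07 and -1.56 ± 0.99, both not passing), but not without replicate 1 (0.151 and 0.241), and at adjusted p = 0.185 and 0.358 with an estimated correlation. In nrg1 the salicylic acid list was higher (median 0.22, or 0.13 with 1 gene at the floor, 0.0246, adjusted p = 0.81 with an estimated correlation) but lower without replicate 2 (0.47). The helper gene list was called higher in adr1 and helperless through ADR1 and ADR1-L1 (median -0.24 in adr1, 1.4e-04 and 0.00761, and adjusted p = 0.0354 and 0.175 with an estimated correlation), though not without replicate 2 (0.0769 and 0.264).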

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

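The tests of explanations for the 3 patterns weighed here were chosen only after the results were seen, as was the fit without 10 libraries, while the interactions, the list tests and the test for libraries far from their group were planned.

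A difference between groups was flagged where an interaction passed. For AvrRps4 at 4 h, edgeR called 1 gene for nrg1 against Col-0, PR2. The salicylic acid list differed from Col-0 by camera in nrg1 (adjusted p = 2.2e-06), adr1 (1.3e-28) and helperless (4.3e-16), and the N-hydroxypipecolic acid list in adr1 (8.0e-07) and helperless (1.2e-05). Between adr1 and nrg1 these lists gave 3.4e-09 and 3.1e-04. With an estimated correlation the calls kept were the adr1 lists (adjusted p = 0.00132 and 0.0458) and the helperless salicylic acid list (0.0354). At 8 h the salicylic acid list gave 3.6e-04 in nrg1, 4.8e-07 in adr1 and 1.1e-12 in helperless, and the N-hydroxypipecolic acid list 4.7e-05 in adr1 and 6.3e-06 in helperless, with none kept (adjusted p of 0.055 to 0.571 with an estimated correlation).

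By gene at 8 h, edgeR called 394 genes for helperless with AvrRps4, or 73 without the 10 libraries. It called 6 for adr1 with AvrRps4 (ADR1, PDF1.2b, AT3G02770, AT3G26470, ADR1-L2 and GER3), 1 with AvrRpt2 (ADR1) and 2 with AvrRpm1 (ADR1 and ADR1-L1), and for helperless 1 with AvrRpt2 (ADR1) and 2 with AvrRpm1 (ADR1 and ADR1-L1), of which those that are not helper genes were named after their values were seen, and none was called without the 10 libraries. In helperless at 0.5 h, outside the planned comparisons, 1 gene passed against EV with AvrRps4, 1 with AvrRpt2 and 1 with AvrRpm1. It was AT5G36790 each time, named after its values were seen (-6.72 ± 1.06, -7.36 ± 1.16 and -7.53 ± 1.15, n = 3), a gene with a near-identical copy, so its counts could not be assigned with certainty.

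The 52 groups were each tested for a library far from the others by Dixon's test, by total counts and by the ratio of ADR1-L1 to ADR1-L2. There were 7 such libraries, where chance gives about 1 in 20 tests. By total counts these were replicate 3 library 1 of adr1 with AvrRpt2 at 4 h (7110813), replicate 3 library 2 of adr1 with AvrRps4 at 8 h (23257821), replicate 3 library 1 of Col-0 with AvrRpt2 at 0.5 h (3574377) and replicate 3 library 2 of helperless with AvrRpm1 at 0.5 h (7671283). By the ratio they were replicate 2 library 2 of Col-0 at T0 (3.67), the library labelled nrg1 with AvrRpm1 at 4 h (24.03) and 1 labelled nrg1 under EV at 8 h (44.18).

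The first pattern is the 10 libraries whose ratio of ADR1-L1 to ADR1-L2 goes against their label, among them both Col-0, both adr1, both helperless and 1 of the 2 nrg1 libraries of replicate 3 under EV at 8 h, where an exchange of Col-0 with adr1 and of nrg1 with helperless stays open. A mixed sample is argued against for the 2 labelled Col-0 and the 3 labelled nrg1 or helperless under EV at 8 h, since AT1G07920 lay between the ranges of both genotypes in 0 of 2 and AT2G41170 in 0 of 3, which excludes only near-equal mixtures. A mislabelled sample has support in both libraries labelled Col-0, where MRD1 lay in the mutants' range alone in 2 of 2. They had 1.18 and 2.38 CPM, against 0 to 0.18 in 70 other infiltrated Col-0 libraries. Support is weaker in those 3, where AT2G41170, a gene picked afterwards, lay in the other genotype's range. These ranges rest on 3 helperless and 5 nrg1 libraries. For the 4 labelled adr1 a mislabelled and a mixed sample cannot be told apart, because AT1G07920 lay outside the adr1 range in all 4 but within that of Col-0 in only 1 (14.49 CPM) and between both in 3 (27.93, 49.16 and 54.94 CPM), while their ratio lay between both ranges in 0 of 4 and MRD1 (0.24, 0.2, 0.17 and 0 CPM) lay below the mutants' median of 1.18 but within their range. For the library labelled nrg1 with AvrRpm1 at 4 h these cannot be told apart either, because the ranges of AT2G41170 overlap (0 of 1) and its ratio of 24.03 lies below one side's range but its 378.18 CPM of ADR1 within it, and no biological explanation was tested.

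The second pattern is the higher ADR1 and ADR1-L1 counts in adr1 and helperless. Reads shared between paralogs are argued against, since the sum of the 3 ADR1 genes was 4500 ± 381 CPM without TMM in adr1 and 326 ± 60.2 in Col-0 under EV at 4 h, a difference of 4170, and moving reads between copies leaves the sum unchanged. Transcription running into neighbouring genes stays open, as the highest difference of a tested neighbour was 4.52 ± 1.02 (AT4G33290, edgeR adjusted p = 0.0682), short of the threshold, and 1 of the 4 measured genes next by identifier had too few counts to test. An effect of the mutations on these transcripts, the biological explanation that the genotypes offer, stays open and was not tested.

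The third pattern is MRD1 and AT1G07920, higher in all 3 mutants than in Col-0. Loss of NRG1 and of ADR1 genes adding up is argued against, for AT1G07920, because helperless minus the sum of both mutants was -5.11 SE on the log2 scale, but it cannot be told apart for MRD1, which had 0 counts in Col-0 at T0. A difference between the Col-0 plants and the parent of the mutants stays open, since the mutants differed from each other by at most 1.6 SE in CPM and the design confounds parent with genotype. For AT1G07920, reads shared between paralogs cannot be told apart from a change in expression, as the sum of its 4 copies at T0 differed by 101 CPM between nrg1 and Col-0 within its spread, while the gene itself gained 90.8. The CPM compared for this pattern carry no TMM factor. An effect of each mutation on its own was not tested apart from the parent.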

How the results depend on the processing

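The fit without 10 libraries against their label was chosen only after the results were seen, while the other alternatives were planned. Of 57 counts, RLE factors moved 0 by over 1.5 times, no filter 2, the replicate block 5, the 10 libraries 11, DESeq2 19, fits on the comparison's groups alone 19 and libraries left unsummed 29, and leaving out replicate 1, 2 or 3 moved 12, 30 and 19. Of 70 lists that passed, 57 did not pass with an estimated correlation, 0 were lost with the replicate block, RLE factors or the 10 libraries left out, and 8, 9 and 3 were lost and 1 each reversed without replicate 1, 2 or 3. Of 232 named genes that passed, 2 were lost with the replicate block, 4 with RLE factors, 6 with no filter, 7 in DESeq2, 1 with libraries unsummed, 39 with fits on the comparison's groups alone, 14 without the 10 libraries and 35, 89 and 46 without replicate 1, 2 or 3. Fits on fewer groups or replicates have fewer residual degrees of freedom, and unsummed libraries count a replicate's 2 libraries as separate samples. Apart from that the cause was not tested. PR1 and MRD1 were at 0 counts in groups where a fold has only a lower bound, at a median of 5477113 counts per library, and the part of depth in this was not tested.

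With the replicate block, a single effect per replicate number over all groups, AvrRps4 in Col-0 at 0.5 h gave 6 genes in place of 3, AvrRps4 in helperless at 8 h 1 in place of 0, the AvrRps4 interactions at 4 h 1 for adr1 and 4 for helperless in place of 0, and the helperless AvrRpt2 interaction at 8 h 3 in place of 1. With no filter the adr1 AvrRps4 interaction at 8 h gave 3 and the helperless AvrRpt2 interaction 2.

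With libraries left unsummed, Col-0 gave 50 genes for AvrRps4 and 7 for AvrRpm1 at 0.5 h, 633 for AvrRps4 and 835 for AvrRpt2 at 4 h and 1901 for AvrRps4 at 8 h. AvrRps4 at 4 h gave 122 in nrg1 and 68 in adr1, and at 8 h 1700, 1576 and 15 in nrg1, adr1 and helperless. AvrRpt2 at 4 h gave 944, 545 and 780, and AvrRpm1 2034 in adr1. The AvrRps4 interactions gave 3, 28 and 117 at 4 h and 11, 110 and 1433 at 8 h for nrg1, adr1 and helperless. Others at 8 h gave 1 for nrg1 with AvrRpm1, 9 for adr1 with AvrRpt2 and 8 and 5 for helperless with AvrRpt2 and AvrRpm1. The mutants against Col-0 gave 17, 76 and 13 at T0, and 11 for adr1 and 16 for helperless under EV.

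With only the comparison's groups in the fit, AvrRps4 gave 0 genes in Col-0 at 0.5 and 4 h and 0 in nrg1 at 4 h and in nrg1 and adr1 at 8 h, and AvrRpm1 at 4 h gave 597, 579 and 1001 in nrg1, adr1 and helperless. The AvrRps4 interactions at 4 h gave 0 for nrg1 and 1 for helperless, those of adr1 at 8 h gave 0, 0 and 0, and those of helperless with AvrRpt2 and AvrRpm1 0 and 0. The mutants gave 1, 1 and 1 at T0 and nrg1 1 under EV.

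DESeq2 gave 1 gene for AvrRpt2 and 2 for AvrRpm1 in Col-0 at 0.5 h. For interactions at 4 h it gave 3, 1 and 1 in nrg1 by effector, 2 in adr1 with AvrRps4, 3, 1 and 1 in helperless and 1, 1 and 1 between adr1 and nrg1. At 8 h it gave 3 in nrg1 with AvrRpt2, 14 and 3 in adr1 with AvrRps4 and AvrRpt2 and 2 in helperless with AvrRpt2. It gave 36 for adr1 and 6 for helperless at T0 and 7 for helperless under EV.

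Without the 10 libraries AvrRps4 at 8 h gave 565 genes in Col-0 and 172 in adr1, and its helperless interaction gave 2 at 4 h and 73 at 8 h. The other interactions at 8 h in adr1 (0, 0 and 0) and helperless (0 and 0) lost every gene. Helperless gave 6 at T0 and 8 under EV. The retained AvrRps4 response at 8 h became 2.9 in Col-0 and 0.27 in helperless, and ADR1 with AvrRps4 in Col-0 at 8 h turned to 0.18.

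With genes chosen without the replicate scored, retained AvrRps4 responses were 1.03, 0.55, -0.17 and -0.4 at 4 h in Col-0, nrg1, adr1 and helperless and 2.42, 1.53 and -0.48 at 8 h in Col-0, nrg1 and helperless, and AvrRpt2 responses 2.69, 2.55, 2.49 and 2.68 at 4 h and 2.96, 3.07, 3.34 and 3.26 at 8 h. RLE factors gave -0.04 for AvrRps4 in helperless at 4 h and 3.11 in Col-0 at 8 h, and a prior count of 0.5 gave 2.92 for AvrRps4 in Col-0 at 8 h, 1.96 for AvrRpt2 in adr1 at 4 h and 2.07 for AvrRpm1 in nrg1 at 8 h.

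Leaving out each replicate, the lowest and highest counts in Col-0 were 0 and 6 for AvrRps4 at 0.5 h, 9 and 188 for AvrRps4, 5 and 356 for AvrRpt2 and 495 and 2008 for AvrRpm1 at 4 h, and 324 and 1282 for AvrRps4 and 1369 and 2422 for AvrRpt2 at 8 h. In nrg1 they were 0 and 71, 21 and 749, and 146 and 1803 at 4 h, and 87 and 2074 for AvrRps4 and 2873 and 4657 for AvrRpt2 at 8 h. In adr1 they were 45 and 208 for AvrRpt2 and 272 and 1270 for AvrRpm1 at 4 h, and 46 and 1227, 3415 and 5032, and 4152 and 6568 at 8 h. In helperless they were 92 and 385 for AvrRpt2 and 432 and 2976 for AvrRpm1 at 4 h, and 0 and 1 for AvrRps4 and 975 and 5203 for AvrRpt2 at 8 h. The AvrRps4 interactions at 4 h ran from 0 to 0 for nrg1 and 0 to 1 for adr1, helperless and adr1 against nrg1. At 8 h adr1 ran from 0 to 25, 0 to 0 and 0 to 0, and helperless from 31 to 265, 0 to 0 and 0 to 3. At T0 the mutants ran from 1 to 2, 1 to 21 and 1 to 2, and under EV from 1 to 2, 1 to 4 and 1 to 5.

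Leaving out each replicate also moved retained responses. At 4 h AvrRps4 ran from 2.37 to 3.95 in Col-0, -0.03 to 2.28 in nrg1, -0.06 to 0.59 in adr1 and 0.07 to 0.13 in helperless, against -0.07 with all 3, and AvrRpt2 from 2.37 to 3.32, 1.94 to 3.24, 1.94 to 3.67 and 2.09 to 3.38. AvrRpm1 ran from 2.06 to 2.35 in Col-0, 1.61 to 2.18 in adr1 and 1.81 to 2.32 in helperless. Without replicate 3 helperless with AvrRps4 gave 0.11. At 8 h AvrRps4 ran from 1.8 to 3.41 in Col-0, 1.4 to 3 in nrg1 and -0.23 to 0.34 in helperless, AvrRpt2 from 2.6 to 3.72, 2.46 to 4.39, 2.6 to 4.62 and 2.85 to 4.35, and AvrRpm1 from 1.58 to 2.17 in nrg1. Of the list calls 3 turned, namely salicylic acid in nrg1 under EV (0.47 without replicate 2, lowest 3.1e-05), salicylic acid in nrg1 with AvrRps4 at 4 h (0.755 without replicate 3, lowest 4.4e-08) and jasmonate in helperless at T0 (0.00284 without replicate 1, lowest 2.2e-15). ADR1 with AvrRps4 in Col-0 at 8 h ran from -3.99 to 0.05.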

Other observations

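The fit without 10 libraries and the splits were chosen only after the results were seen, while the list tests were planned.

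Before infiltration, touch genes were higher in adr1 than in Col-0 as a list, with TCH4 at 1.93 ± 0.58 and TCH2 at 1.16 ± 0.38 on the log2 scale (edgeR adjusted p = 0.437 for TCH4, n = 3). By gene 0 of 3 passed (2 adjusted over the list alone, camera adjusted p = 5.9e-08, and adjusted p = 0.00224 with an estimated correlation). In nrg1 the median was 0.90, with TCH4 at 1.26 ± 0.57 and 0 of 3 passing (camera adjusted p = 3.3e-05, and adjusted p = 0.0372 with an estimated correlation). Jasmonate genes were lower at T0 in nrg1, where VSP1 stood at -4.14 ± 1.3 and JAZ10 at -2.38 ± 0.63. Here 0 of 26 passed (8 lower adjusted over the list alone, median -0.97, camera adjusted p = 3.0e-23, and adjusted p = 0.055 with an estimated correlation). In helperless the jasmonate median was -0.50, with VSP1 at -2.91 ± 1.13 and VSP2 at -1.74 ± 1.05 (2.3e-07, and adjusted p = 0.529 with an estimated correlation), and the list turned upward without replicate 1 (0.00284).

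At 8 h in Col-0 both other effectors also changed groups outside salicylic acid. With AvrRpt2, 10 of 12 camalexin genes rose, PAD3 by 3.29 ± 0.73 (median 2.36, camera adjusted p = 9.9e-06, and adjusted p = 0.376 with an estimated correlation). So did 13 of 30 genes of pattern-triggered immunity, 15 adjusted over the list alone (1.1e-05, and adjusted p = 0.706 with an estimated correlation). In the salicylic acid list 15 of 21 rose and 1 fell, PBS3 by 4.45 ± 0.69 and EDS5 by 3.76 ± 0.58 (6.5e-08, and adjusted p = 0.21 with an estimated correlation). With AvrRpm1, 17 of 26 jasmonate genes rose, 20 adjusted over the list alone, ANAC055 by 2.80 ± 0.61 (1.4e-04, and adjusted p = 0.737 with an estimated correlation). The camalexin list had 8 of 12 up, PAD3 by 4.04 ± 0.75 (0.0152, and adjusted p = 0.787 with an estimated correlation), and the abscisic acid list 10 of 16, 12 adjusted over the list alone (0.00258, and adjusted p = 0.793 with an estimated correlation). The salicylic acid list had 7 up and 2 down with AvrRpm1, DLO1 rising by 5.22 ± 0.81 (camera adjusted p = 0.146).

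The splits of the same 6 samples into 3 and 3 number 10 with the real one, too few for a share under 0.05. With AvrRps4, AvrRpt2 and AvrRpm1 in Col-0 the real counts and the highest of other splits were 131 and 23, 489 and 0, and 2125 and 202 at 4 h, and 996 and 3, 2901 and 9, and 5698 and 4 at 8 h. For EV against T0 they were 4595 and 7, 9742 and 17, and 8316 and 33. In nrg1 they were 32 and 14, 520 and 17, and 1672 and 187 at 4 h, and 5126 and 9 for AvrRpt2 and 6301 and 50 for AvrRpm1 at 8 h. In adr1 they were 256 and 0 for AvrRpt2 and 1355 and 87 for AvrRpm1 at 4 h, and 439 and 262, 5626 and 47, and 6453 and 10 at 8 h. In helperless they were 456 and 2 and 2140 and 447 at 4 h for AvrRpt2 and AvrRpm1, and 3899 and 282 and 7100 and 265 at 8 h. Under EV at 4 h the mutants gave 3 and 0, 4 and 0, and 4 and 1. In all of these 1 split of 10, the real one, gave a count as large.

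In the others the real split was not alone. As many genes or more came from 2 of 10 splits for AvrRps4 at 0.5 h (real 3, highest other 11). Where the real count was 0, all 10 are as large whatever the data, so nothing follows, as for AvrRpt2 (0 and 1) and AvrRpm1 (0 and 145) at 0.5 h, AvrRps4 at 4 h in adr1 (0 and 22) and helperless (0 and 0), and AvrRps4 at 8 h in helperless (0 and 10). For AvrRps4 at 8 h in nrg1 it was 3 (656 and 2134), where the highest put replicate 1 with AvrRps4 beside replicates 2 and 3 under EV. At T0 it was 2 for nrg1 (3 and 4), 2 for adr1 (15 and 33) and 4 for helperless (2 and 19). These splits ignore the replicate numbers, which pair the samples in 16 of these contrasts. There 4 splits part all 3 pairs, as the real one does, and the highest of the others among them gave 0 genes at T0 and under EV at 4 h for each mutant, 2 for AvrRps4 at 0.5 h and 16 for EV at 4 h against T0. The splits with the higher counts at T0 kept 2 pairs together. Lists passing at 4 h in Col-0 numbered 3 with AvrRps4 (10 of 10 splits as large, highest other 10), 9 with AvrRpt2 (3 of 10, 11) and 7 with AvrRpm1 (2 of 10, 8). These numbers do not set the real groups apart.

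For interactions 25 splits were counted, the real one among them, and a chance split of the samples was not excluded for any with a real count above 0. Genotype labels were exchanged separately among the effector samples and among the EV samples. A split may therefore keep the real grouping in 1 of these, so a match to the real count does not show chance either. A real count of 0 is met by all 25 whatever the data, so there the splits say nothing. At 4 h the count of 1 for nrg1 with AvrRps4 was met by 12 splits (highest other 15), and the counts of 0 had highest others of 13 and 142 for nrg1, 52, 6 and 628 for adr1, 41, 47 and 131 for helperless and 128, 0 and 832 between adr1 and nrg1. At 8 h the counts of 0 in nrg1 had highest others of 930, 4 and 6. The counts of 6, 1 and 2 in adr1 were met by 4, 9 and 4 splits (247, 121 and 4). Those of 394, 1 and 2 in helperless were met by 5, 13 and 2 splits (3299, 429 and 10).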
